A study of Rattus norvegicus with 5 samples.

How the data were processed

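RNA of 3 metastatic lung nodules, 1 irradiated primary tumour and 1 non-irradiated primary tumour was measured on 1-colour (Cy3) Agilent rat expression arrays, 1 array per sample and 5 arrays on 1 slide; per the labels the hosts were 6 weeks old and RNA was prepared with Qiagen RNeasy and the Quick Amp kit. The deposited intensity values are spot signals that, per the file headers, Agilent Feature Extraction 11.0 corrected by subtracting the background and detrending within each array, with nothing adjusted between arrays. The deposited spot flags (well above background, saturated, outlier) are other values of 0 or 1, set by the same software per the file headers. A deposited matrix holds log2 values of 18502 probes, made by the authors in a way the file does not state. Its sorted columns differed by at most 0.000749, each median was 9.74, its columns correlated at 0.9996 to 0.9999 with the log2 signal of their own array, and 18499 of its probes were well above background on all 5 arrays, as quantile normalization after such a filter would give. No probe sequences were used here, and the array design rests on an older rat genome than the gene table, so no coordinates are given.

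Each array held 58717 gene spots and 4259 control spots. Outlier spots (0.603 to 0.865% of the gene spots of an array) were left out, and 0 were saturated. The log2 signals of the spots of a probe were averaged, and each array was scaled by subtracting the 75th percentile of its own log2 signals over non-control probes. Of 30367 probes, 4 had no usable spot on some array and 30363 were used. Gene names were taken through the RefSeq accession of each probe, since the files held no gene name column, which named 18354 probes (60.4%) with 15442 symbols and 0 probes with several. The other 12009 probes stayed features without a name. Probes were tested when well above background on all arrays of at least 1 group, and the brightest probe stood for a gene. This left 18913 features, 11104 named and 7809 unnamed. Several probes were tested for 1866 genes, of which 0 had calls in opposite directions against the irradiated primary and 14 had probes that differed in sign by more than 0.5 on the log2 scale. The lowest well-above-background levels, used for lower bounds of folds, were -6.46, -6.69 and -6.77 for nodules 1, 2 and 3, -6.03 for the irradiated and -6.12 for the non-irradiated primary.

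Nodules were compared with each primary by limma 3.58.1 in R 4.3.3 (3 group means, eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05). The residual spread comes from the 3 nodules alone. The primaries, with 1 array each, were compared by log2 differences of at least 1 among 18442 features well above background on at least 1 of both arrays. The same count for each pair of nodules stands beside it. An overlap of calls against both primaries was set beside the product of the list sizes and 100 simulations of unchanged groups that share the nodules.

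Gene lists written before the data were examined covered 36 groups. They were p53 targets, DNA repair, cell cycle, interferon-stimulated genes, class I and class II antigen presentation, cytokines and chemokines, complement and acute phase, hypoxia, glycolysis, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, unfolded protein response, heat shock and immediate early genes, collagens and matrix, matrix proteases, epithelial-mesenchymal transition, angiogenesis and glial markers. Markers of alveolar type 1 and type 2, airway, endothelial, pericyte, fibroblast, macrophage, neutrophil, T and NK, B, mast and platelet, erythroid, skeletal muscle, skin and fat cells and housekeeping genes completed them. Lists of at least 5 measured members were tested with limma's camera (preset correlation 0.01, adjusted over the lists), with an estimated correlation and with fry. For the primaries the median of a list was placed among 10000 random lists of equal size matched in 10 bins of expression, and counted as outside below percentile 2.5 or above 97.5. Members were also counted by limma with p adjusted over the list alone.

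The named genes followed a rule set before the data were examined. It took the 8 largest changes each way against the irradiated primary among called genes with all nodules on the same side and well above background, and the 10 largest differences each way between the primaries. To each it added up to 4 lower bounds each way, where a gene was well above background in 1 group only, and members of the lists. Values against the non-irradiated primary are given for some of the genes so named. A few genes that the rule covers are not reported here. The comparisons, tests, lists, rule and alternatives were all set before the data were examined, except that the planned normexp correction of mean spot signals was run on median spot signals because the files hold no mean column. The median of the 3 pairs of nodules as summary of their counts was also chosen later, as were 5 of the 6 tests of explanations in the closing observations.

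The fit was tested on simulated data in 20 runs with the spread of these arrays and 200 changed genes in 18913. With 3 nodules against 1 primary it found 2.16% of the genes changed 2-fold, 44.3% of those changed 4-fold and 68.3% of those changed 8-fold, with 4.33% of its calls false. With 2 nodules it found 0.0746%, 5.15% and 22.7%, with 6.58% of its calls false. The simulated primary was given the spread of the nodules, so the false shares hold only where a real primary varies like them. The simulation also differed from the arrays: 2 nodules gave it fewer calls than 3 (395 against 1593), but the arrays gave more without nodule 1 (3232 against 704). Lists of 30 members shifted in the simulation were found in 20 of 20 runs by camera (nodules against the non-irradiated primary) and by the percentile (between the primaries). Of 400 unshifted lists, camera passed 5 at an unadjusted p under 0.05 (1.25%) and 23 lay outside the percentile limits (5.75%). The simulated genes varied independently of each other, so these shares do not hold for lists whose members vary together. On the real arrays the estimated correlation against the irradiated primary was 0.77 for cholesterol synthesis, 0.68 for T and NK cell markers and 0.51 for cell cycle genes. It was 0.156 for skeletal muscle markers and 0.151 for cytokines and chemokines. For the other called lists it ran from -0.0509 (glycolysis) to 0.0425 (interferon-stimulated genes). All these estimates rest on 2 residual degrees of freedom. Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the array median, no filter on dim probes, probes well above background on all 5 arrays, every probe a feature, the deposited matrix, no intensity trend, stricter fold thresholds and leaving out each nodule. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.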

Results

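Tumours of C6-L cells, a rat glioma line, were grown in nude mice and measured on 5 single-colour arrays. These were 3 metastatic lung nodules and 1 irradiated primary tumour, all taken 6 weeks after γ-irradiation, and 1 non-irradiated primary tumour taken 6 weeks after xenograft. The number of arrays limits the precision: each primary is 1 array, and every p-value against it rests on the spread between the 3 nodules, which the lone primary was assumed to share. On each array 69.8 to 73.5% of the gene spots were well above background and 0 were saturated. Correlations over probes were 0.986 to 0.995 between nodules, 0.973 to 0.978 between a nodule and the irradiated primary, and 0.961 to 0.970 between a nodule and the non-irradiated primary. The p-values measure only the spread between these samples, since the labels do not say whether the nodules came from separate animals. All arrays sat on 1 slide with the nodules in a row of their own, so slide row and group cannot be told apart. The probes are rat sequences and the host is a mouse, so signal from host cells was read through probes of another species.

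The first comparison of the series sets the lung nodules against the irradiated primary. By camera with a preset correlation, the 3 nodules held far less RNA of skeletal muscle genes than that tumour, less RNA of interferon-stimulated genes, chemokines, the hypoxia response, glycolysis and the unfolded protein response, and more RNA of cholesterol synthesis genes. Of 12 lists called in this way, 6 passed by fry, chemokines and cholesterol synthesis not among them, and 0 passed with an estimated correlation (smallest adjusted p = 0.289). That last test rests on the 2 residual degrees of freedom, so its misses do not show that correlation between members undid the calls. The estimate lay under the preset 0.01 for hypoxia (-0.0172) and glycolysis (-0.0509), both at camera adjusted p = 0.289. For cholesterol synthesis it lay above (0.77). The fast muscle light chain Myl11 fell by 8.24 on the log2 scale (SE 0.25, limma adjusted p = 0.00394), the ubiquitin-like protein Isg15 fell by 4.42 (SE 0.21, adjusted p = 0.00661) and the glucose transporter Slc2a1 fell by 2.96 (SE 0.25, adjusted p = 0.0139). The desaturase Scd, which makes monounsaturated fatty acids, rose by 3.09 (SE 0.24, adjusted p = 0.0128). Each of these genes lay on the same side of the primary in 3 of 3 nodules, which the naming rule required of Myl11 and Scd. Among 18913 features tested, 172 rose and 532 fell, and 140 and 425 of them differed at least 2-fold. The calls of single genes hung on the choice of nodules: limma called 704 with all 3, 0 without nodule 2 (2705 at an unadjusted p under 0.05, smallest adjusted p = 0.0501), 3232 without nodule 1 and 191 without nodule 3. Scaling to the array median left 438 and a variance model without an intensity trend left 399.

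Skeletal muscle transcripts gave the largest differences. Of 21 muscle markers measured, 14 fell, 0 rose and 7 did not pass (17 fell when adjusted over the list alone), with a median of -4.27 (camera adjusted p = 5.58e-19; adjusted p = 0.289 with an estimated correlation; fry adjusted p = 0.00976). Acta1 fell by 8.56 (SE 0.66), Ckm fell by 6.87 (SE 1.03), Myoz1 fell by 6.41 (SE 0.21), Tnnc2 fell by 6.38 (SE 1.00), Pvalb fell by 5.64 (SE 0.29), Tnnt3 fell by 4.27 and Tnni2 fell by 3.41, at limma adjusted p-values from 0.00394 (Tnnt3, Tnni2, Myoz1) to 0.0483 (Tnnc2). Ankrd2, a muscle ankyrin protein outside the list, fell by 6.67 (SE 0.19, adjusted p = 0.00394). Ckm and Tnnc2 each lost their call in 5 other processing settings (adjusted p up to 0.0828 and 0.0878). The fast myosin heavy chain Myh4 was at least 522-fold lower and the myosin-binding protein Mybpc1 at least 111-fold lower. Such bounds set the mean of the bright group against the mean of the dim group, in which each dim array was raised to its lowest well-above-background level where the probe lay under it. Without nodule 2 the adjusted p-values of all genes named against the irradiated primary lay between 0.0501 and 0.218, so none of these gene calls held, while the muscle list kept its call. Without nodule 3, 46 of the 78 genes so named lost their call (adjusted p up to 0.131).

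Some interferon-stimulated, chemokine, class I and T cell genes fell in the nodules. Of 31 interferon-stimulated genes, 10 fell, 0 rose and 21 did not pass (15 fell over the list alone), with a median of -0.79 (camera adjusted p = 1.46e-09; adjusted p = 0.289 with an estimated correlation; fry adjusted p = 0.0261). Beside Isg15, Cxcl10 fell by 2.47 (adjusted p = 0.013), Usp18 fell by 1.98 (adjusted p = 0.04) and Gbp2 fell by 1.59 (adjusted p = 0.0283). Rsad2 was at least 21.4-fold and Cxcl11 at least 14.2-fold lower. Of 26 cytokines and chemokines, 4 fell and 22 did not pass (14 fell over the list alone), with a median of -0.63 (camera adjusted p = 9.68e-07; adjusted p = 0.466 with an estimated correlation, fry adjusted p = 0.145). The neutrophil attractant Cxcl1 fell by 3.61 (SE 0.26, adjusted p = 0.0111), Ccl2 fell by 2.09 (adjusted p = 0.0329), Ccl7 fell by 1.79 (adjusted p = 0.0342) and Cxcl2 was at least 5.53-fold lower. Class I antigen presentation had a median of -0.34 over 17 genes (camera adjusted p = 0.000375; adjusted p = 0.309 with an estimated correlation, fry adjusted p = 0.00976): RT1-CE16 fell by 0.74 and RT1-A2 fell by 0.71, 15 did not pass, and 4 fell over the list alone. Mill1, a class I-like gene, was at least 80.7-fold lower. Among 16 T and NK cell markers, 3 fell, among them Cd7 by a log2 change of -2.88 (adjusted p = 0.0111) and Cd2, which was dim in the nodules. Over the list alone 5 fell. The T and NK cell list had a median of -0.41 (camera adjusted p = 0.00353; adjusted p = 0.872 with an estimated correlation, fry adjusted p = 0.189) and lost its call on probes well above background on all 5 arrays (adjusted p = 0.221) and on the deposited matrix (adjusted p = 0.227). Its median was -0.22 without nodule 3. Macrophage markers, measured beside them, had a median of -0.14, and 0 of 25 passed limma (camera adjusted p = 0.443). Usp18, Gbp2, Ccl2, Ccl7, Cxcl2, RT1-A2, RT1-CE16 and Cd2 lost their call in 1 to 4 other processing settings (adjusted p from 0.0509 to 0.121). Without nodule 2 no gene call here held (adjusted p from 0.0501).

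Hypoxia and glucose metabolism genes were lower too. In the hypoxia list 8 of 28 genes fell, 0 rose and 20 did not pass (17 fell and 2 rose over the list alone), with a median of -0.98 (camera adjusted p = 1.46e-09; adjusted p = 0.289 with an estimated correlation; fry adjusted p = 0.00976). Beside Slc2a1, Angptl4 fell by 2.74 (adjusted p = 0.011), Slc2a3 fell by 2.40 (adjusted p = 0.0357), the carbonic anhydrase Car9 fell by 2.07 (adjusted p = 0.037), Hk2 fell by 1.78 (adjusted p = 0.0192), Bnip3 fell by 1.44, P4ha1 fell by 1.33 and Aldoa fell by 1.02. In glycolysis 3 of 20 genes fell and 17 did not pass (12 fell over the list alone), with a median of -0.71 (camera adjusted p = 8.69e-07; adjusted p = 0.289 with an estimated correlation; fry adjusted p = 0.00112); all 3 are hypoxia members as well. The unfolded protein response had a median of -0.51, with 4 of 20 genes lower, 16 not past the test and 13 lower over the list alone (camera adjusted p = 5.14e-08; adjusted p = 0.289 with an estimated correlation; fry adjusted p = 0.00976). Its member Trib3 fell by 2.84 (adjusted p = 0.016), Ddit3 fell by 1.29 (adjusted p = 0.0477), Asns fell by 0.99 (adjusted p = 0.0342) and Atf3 was at least 16.4-fold lower. Skeletal muscle markers, from a tissue that also runs on glycolysis, moved the same way in the same comparison (median -4.27). Slc2a3, Car9, Bnip3, P4ha1, Aldoa, Ddit3, Asns and Atf3 lost their call in 1 to 4 other processing settings (adjusted p from 0.0507 to 0.095). Without nodule 2 these gene calls were lost (adjusted p from 0.0501), and the lists kept theirs.

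With all 3 nodules, cholesterol synthesis was the list with the largest median rise. All 23 measured genes lay higher in the nodules, 4 of them past the test (15 over the list alone) and 19 not, with a median of 1.15 (camera adjusted p = 1.46e-09; adjusted p = 0.706 with an estimated correlation; fry adjusted p = 0.261). Hmgcs1 rose by 1.61 (adjusted p = 0.0351), Idi1 by 1.54 (adjusted p = 0.047), Sqle by 1.47 (adjusted p = 0.0448) and the regulator Srebf2 by 1.18 (adjusted p = 0.0473). Cell cycle genes lay slightly higher, with a median of 0.26 over 31 genes (camera adjusted p = 0.00752; adjusted p = 0.872 with an estimated correlation, fry adjusted p = 0.539), but 0 passed limma, also over the list alone, and without nodule 3 the median was 0.14 and the call was lost (adjusted p = 0.0895). The p53 targets Plk2 and Ccng1 both fell, by log2 changes of -1.37 and -1.16 (both adjusted p = 0.0381). They belong to 24 measured p53 targets with a median of -0.31, of which 22 did not pass and 5 fell over the list alone (camera adjusted p = 0.00927; adjusted p = 0.429 with an estimated correlation, fry adjusted p = 0.145; adjusted p = 0.0882 with no filter on dim probes). DNA repair genes had a median of 0.13 over 22 genes with 0 past limma (camera adjusted p = 0.566). Each of the named cholesterol and p53 genes lost its call in 2 to 5 other processing settings (adjusted p from 0.0509 to 0.0969). Without nodule 2 no gene call in these lists held (adjusted p from 0.0501).

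Matrix genes moved in both directions. Elastin (Eln) rose by 1.85 (adjusted p = 0.008) and Col3a1 by 0.84 (adjusted p = 0.0477), while Tnc fell by 2.62 (adjusted p = 0.0193) and Thbs1 fell by 1.99 (adjusted p = 0.0306), among 28 collagen and matrix genes with a median of 0.31. That list (6 rose and 3 fell over the list alone) passed camera (adjusted p = 0.0233; adjusted p = 0.466 with an estimated correlation, fry adjusted p = 0.22). It did not pass with quantile normalization (adjusted p = 0.0507), every probe kept (adjusted p = 0.0587), no intensity trend (adjusted p = 0.0545), probes well above background on all 5 arrays (adjusted p = 0.0748) or the deposited matrix (adjusted p = 0.117). Among 27 matrix proteases and inhibitors 4 fell, 1 rose and 22 did not pass. Mmp3 fell by 4.73 (adjusted p = 0.016), Mmp10 was at least 36.5-fold and Mmp13 at least 6.35-fold lower, and Mmp23 rose by 2.21 (adjusted p = 0.0286). The list's median of -0.38 gave camera adjusted p = 0.0701. In the immediate early and heat shock list of 27 genes, Ccn1 fell by 2.36 (adjusted p = 0.0236), Myc fell by 1.86 (adjusted p = 0.0365), Hspb1 fell by 1.62 (adjusted p = 0.0128) and Atf3 fell as given above. Nr4a2 rose by 1.16 and Klf6 by 0.79, and the median was -0.11 (camera adjusted p = 0.139). Complement C3 rose 5.65-fold (adjusted p = 0.0396) and ceruloplasmin (Cp) fell by 1.30 (adjusted p = 0.0376), with 16 of 18 complement and acute phase genes not past the test. The glioma and glial markers showed 1 rise, Gpm6a (at least 3.60-fold higher), and 1 fall, Tnc, among 24 genes (camera adjusted p = 0.619). Col3a1, Mmp10, Mmp13, Myc, Nr4a2, Klf6, C3, Cp and Gpm6a, and Atf3 as well, lost their call in 1 to 5 other processing settings (adjusted p from 0.0507 to 0.105). Without nodule 2 none of these gene calls held (adjusted p from 0.0501).

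Other genes with large changes, apart from the skin marker Dmkn, belonged to none of the gene lists. Fam180a rose by 4.06 (SE 0.31, adjusted p = 0.0117), Irag1 by 3.56 (SE 0.18, adjusted p = 0.00661), Ica1 by 2.91 (SE 0.29, adjusted p = 0.0196), the Wnt antagonist Nkd1 by 2.89 (SE 0.24, adjusted p = 0.0137) and the guidance ligand Slit3 by 2.69 (SE 0.29, adjusted p = 0.025). Nkain4, Klhl38, Slc7a10 and Dmkn, the last a skin marker, were at least 6.39-fold, 6.11-fold, 5.37-fold and 4.10-fold higher. The aldehyde dehydrogenase Aldh3a1 fell by 5.35 (SE 0.21, adjusted p = 0.00588), and the Wnt ligand Wnt10a was at least 273-fold lower. Against the non-irradiated primary Aldh3a1 differed by only 0.13 (limma adjusted p = 0.688), and Wnt10a was at least 3.58-fold lower. Nkain4, Slc7a10 and Dmkn lost their call in 2 to 5 other processing settings (adjusted p from 0.0518 to 0.119). Every one of these calls was lost without nodule 2 (adjusted p from 0.0501).

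**Figure D1:**
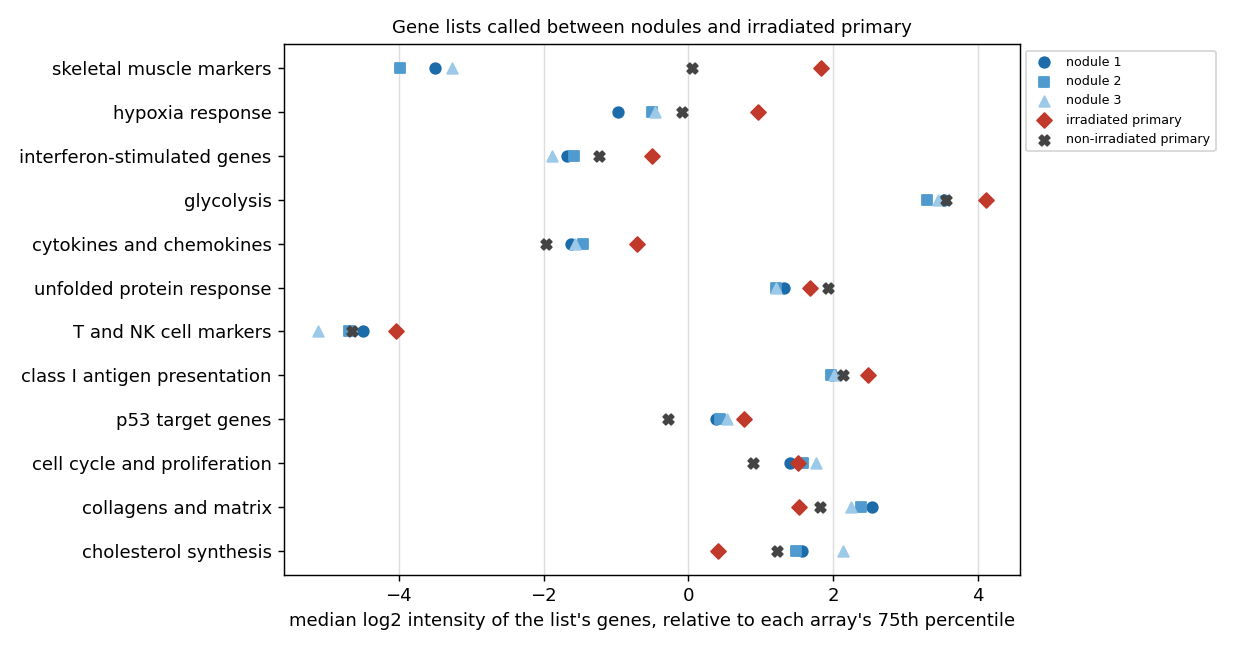
Median log2 intensity of 12 gene lists on each of the 5 arrays, relative to the array's 75th percentile. The lists shown are those called by camera between the 3 nodules and the irradiated primary.

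Markers of lung and heart differed between the nodules themselves. The club cell gene Scgb1a1 stood at 4.11 and 3.09 on the log2 scale in nodules 1 and 2, and at -5.27 in nodule 3, where the irradiated primary read -5.41 and the non-irradiated primary -5.27. The surfactant protein Sftpd stood at 4.46, 2.27 and -6.00 in nodules 1, 2 and 3, and the alveolar receptor Ager at 1.88, -0.18 and -3.16. In turn the heart myosins Myh6 and Myh7 read 3.87 and 2.60 in nodule 3, against -2.84 and -3.21 in nodule 1 and -3.03 and -3.90 in nodule 2. The irradiated primary lay between them, with -0.34 for Myh6 and -0.70 for Myh7. Against the irradiated primary, 0 of 13 alveolar type 1 markers (median 0.61, camera adjusted p = 0.0774) and 0 of 8 alveolar type 2 markers (median 0.25, adjusted p = 0.98) passed limma, and of 12 airway markers 1 fell, the ciliary gene Tekt4 (log2 change -3.48, adjusted p = 0.023; list median 1.01, camera adjusted p = 0.29). Camera called the type 1, type 2 and airway lists without nodule 3 (medians 0.94, 0.55 and 1.88), and without nodule 1 the type 1 and type 2 medians were 0.30 and 0.040. The haemoglobin gene Hbb-b1 lay higher by 2.40 in the nodules (adjusted p = 0.0604), and of 13 erythroid markers Alas2 rose by 2.86 (SE 0.46, adjusted p = 0.0499) with 5 up and 1 down over the list alone (median 0.88, camera adjusted p = 0.167). That median was 0.44 with dim values at their bounds, 0.49 without nodule 1 and 0.082 with no filter on dim probes. Fap, a fibroblast protease, rose by 3.17 (SE 0.35, adjusted p = 0.0256) and was the 1 of 12 fibroblast and mesothelial markers to pass. Desmin (Des) fell by 4.40 (adjusted p = 0.0091) as the 1 of 16 pericyte and smooth muscle markers. The call of Alas2 was also lost in 5 other processing settings (adjusted p from 0.0502 to 0.0903). Without nodule 2 the calls of Tekt4, Alas2, Fap and Des were lost (adjusted p from 0.0501).

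**Figure D2:**
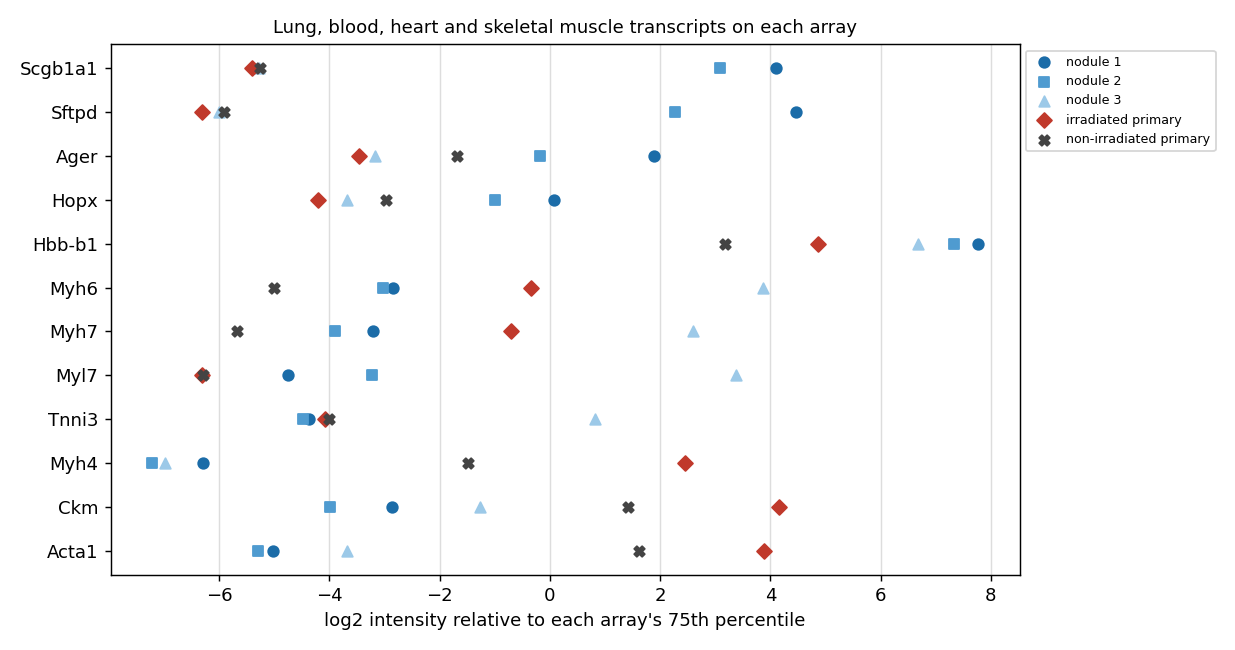
Log2 intensity of lung, blood, heart and skeletal muscle genes on each of the 5 arrays, relative to the array's 75th percentile.

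Set beside the non-irradiated primary, the nodules showed, by camera with a preset correlation, higher RNA of proliferation genes, p53 targets, cholesterol synthesis and macrophage markers, and again less skeletal muscle RNA. With an estimated correlation all 5 of these lists had adjusted p = 0.991, and fry called 0 lists. Of 31 cell cycle genes 18 rose and 0 fell (25 and 1 over the list alone), with a median of 0.92 (camera adjusted p = 4.22e-09). Kif11 rose by 1.78 (adjusted p = 0.0126), Kif20a by 1.66 (adjusted p = 0.0107), Tpx2 by 1.51, Plk1 by 1.44 and Mki67 by 1.27. Of 24 p53 targets 11 rose and 1 fell (13 and 2 over the list alone; median 0.85, camera adjusted p = 0.0155). The death receptor Fas rose by 1.92 (adjusted p = 0.0188), the p53 inhibitor Mdm2 by 1.53 (adjusted p = 0.0131), Zmat3 by 1.41 (adjusted p = 0.0115), the cyclin-dependent kinase inhibitor Cdkn1a by 1.24 (adjusted p = 0.0131) and Bax by 0.87. Tigar fell by 0.56 (adjusted p = 0.0465). Cholesterol synthesis rose in 5 of 23 genes and fell in 0 (the same counts over the list alone; median 0.64, and 0.37 without nodule 3; camera adjusted p = 0.0155), with Ebp up by 1.41, Sqle by 1.33, Fdft1 by 1.13 and Hmgcs1 and Srebf2 each by 0.89. Of 25 macrophage markers 10 rose and 3 fell (13 and 4 over the list alone; median 0.90, and 0.53 with normexp; camera adjusted p = 0.0155). Siglec1 rose by 2.69, Aif1 by 2.38, the Fc receptor Fcgr1a by 1.69, Adgre1 by 1.51 and C1qb by 1.20. The scavenger receptor Cd163 fell by 2.54, Gpnmb fell by 1.89 and Cd68 fell by 1.12. The probes of Aif1 disagreed, and their mean gave -0.59 (adjusted p = 0.343). Skeletal muscle markers fell in 13 of 21 genes and rose in 0 (16 and 0 over the list alone; median -2.64, camera adjusted p = 4.22e-09). Camera called 8 lists without nodule 1 and 9 with no filter on dim probes. Of 61 genes named against this primary, all lost their call without nodule 2 (limma adjusted p from 0.0542 to 0.163) and 25 without nodule 3 (up to 0.131), with 9 lost without an intensity trend, 7 with median scaling, 6 with no filter on dim probes, 4 with quantile normalization, and 2 each on the deposited matrix and with every probe kept.

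Single genes moved in larger numbers against the non-irradiated primary: 1839 rose and 1673 fell, 1029 and 1094 of them at least 2-fold. The largest rises among genes named above were Irag1 by 6.10 (limma adjusted p = 0.00688) and Fam180a by 5.57 (adjusted p = 0.00761), and Alas2 rose by 4.40, C3 by 3.61 (adjusted p = 0.0126), Nkd1 by 2.95 and Scd by 2.32. Hbb-b1 rose by 4.09 (adjusted p = 0.0131) and Hbb by 4.53 (adjusted p = 0.0151), and the ciliary gene Tppp3 rose by 4.19 (adjusted p = 0.0074). Myl11 fell by 6.07, Acta1 fell by 6.28, Ankrd2 fell by 5.20 and Myoz1 fell by 4.10. Mmp3 fell by 6.46 (adjusted p = 0.00872), Mmp7 fell by 4.62 (adjusted p = 0.0221), Trib3 fell by 3.13, Asns fell by 2.04, Slc2a3 fell by 2.20 and Slc2a1 fell by 1.80. Within the interferon-stimulated genes 5 rose and 5 fell of 31 (median -0.14, camera adjusted p = 0.806), with Irf7 up by 2.77 and Oas1a by 2.25. Hypoxia and glycolysis had medians of -0.17 (camera adjusted p = 0.412; -0.25 without nodule 2) and -0.093 (adjusted p = 0.836). Without nodule 2 limma called 0 genes against this primary (5008 at an unadjusted p under 0.05, smallest adjusted p = 0.0542), with 6472 called without nodule 1 and 296 without nodule 3.

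Both primaries together placed 302 features on the same side, 104 higher and 198 lower in the nodules, among them Myl11, Mmp3, Slc2a1 and Trib3 below and Irag1, Fam180a, Scd, C3 and Sqle above. Another 11 features moved in opposite directions. Cxcl1, Angptl4 and Ccng1, which lay below the irradiated primary in the nodules, read 1.45, 0.955 and 0.88 above the non-irradiated primary. Independent lists of these sizes would share 16.7 rises and 47.1 falls, and simulated unchanged groups that share the nodules gave a mean of 0.05 and at most 2 in 100 runs. Those simulations called at most 5 features against either primary, so they do not show how much of the excess comes from sharing. Part of the excess may come from the nodules that both comparisons share. The count was 0 without nodule 2, 73 without nodule 3, 1663 without nodule 1 and 200 without an intensity trend.

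The second comparison of the series, irradiated against non-irradiated primary, has 1 array on each side. It is given as differences with no test, apart from 1 alternative contrast that lends both tumours the spread of the nodules. The irradiated tumour was timed from irradiation and the other from xenograft, so irradiation and time of growth cannot be told apart. In the irradiated tumour, p53 targets, interferon-stimulated genes, macrophage markers and skeletal muscle genes lay higher, and cholesterol synthesis genes lay lower. Of 24 p53 targets 12 lay at least 2-fold higher and 0 lower (median 0.98, above all of 10000 matched random lists, percentile 100), among them the stress cytokine Gdf15 by 2.40, Ccng1 by 2.04, Zmat3 by 2.02, Mdm2 by 1.87, Fas by 1.52 and Cdkn1a by 1.43. Interferon-stimulated genes had a median of 1.26 (percentile 100; 18 of 31 at least 2-fold higher, 0 lower), with Irf7 higher by 3.56, Isg15 by 3.28 and Oas1a by 2.89. Among cytokines Tnf lay higher by 2.83, Ccl7 by 2.18 and Ccl2 by 1.11 (median 0.59, percentile 99.99; 10 of 26 higher, 1 lower). Macrophage markers had a median of 0.93 (percentile 100; 10 of 24 higher, 2 lower): Siglec1 lay higher by 3.24 and Fcgr1a by 2.27, whereas Gpnmb read -1.69 and Cd163 -1.15. Cell cycle genes had a median of 0.70 (percentile 100; 5 of 31 higher, 0 lower), Ccne1 by 1.40 and Aurka by 1.23, and DNA repair genes one of 0.37 (percentile 98.3), Brca1 by 1.03. The cell cycle, p53 and macrophage lists lay higher in the nodules too (medians 0.92, 0.85 and 0.90), but against the same non-irradiated array. A low reading of these genes on that 1 array would give both rises, so the 2 comparisons are not separate evidence.

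In the same pair, hypoxia genes had a median of 0.60 (percentile 100; 8 of 28 at least 2-fold higher, 0 lower), with Angptl4 higher by 3.69, Hmox1 by 2.27, Ndrg1 by 1.66 and P4ha1 by 1.60, and glycolysis one of 0.51 (percentile 99.98; 7 of 20 higher), with Slc2a1 by 1.16. Skeletal muscle markers had a median of 1.83 (percentile 100; 16 of 21 higher, 0 lower), Ckm by 2.74, Acta1 by 2.28 and Myl11 by 2.16. Immediate early and heat shock genes had a median of 0.56 (percentile 100; 9 of 27 higher), Dusp1 by 3.31, Hsph1 by 2.18 and Fos by 1.43. Angiogenesis signalling stood at 0.65 (percentile 100; Notch1 by 1.85, Vegfa by 0.65) and complement at 0.87 (percentile 100; Cfb by 1.97). Pericyte and smooth muscle markers stood at 0.64 (percentile 99.8), with 6 of 15 at least 2-fold higher and 1 lower. Among them Des lay higher by 1.99, but Pdgfrb read -2.09. Epithelial-mesenchymal transition stood at 0.41 (percentile 99.3; Krt8 by 2.29), T and NK cell markers at 0.48 (percentile 98.3), and the unfolded protein response at 0.34 (percentile 99.2; Hsp90b1 by 1.21, but Asns at -1.05). On the other side, cholesterol synthesis had a median of -0.63 (percentile 0; 6 of 23 at least 2-fold lower, 1 higher), with Hsd17b7 at -1.76, Insig1 at -1.34 and Idi1 at -1.24. Alveolar type 2 markers had one of -0.78 (percentile 0.42), but of 6 genes 2 lay at least 2-fold higher, among them Lpcat1 (1.57), and 2 lower, among them Napsa (-2.29). Collagens and matrix genes split, 5 of 26 higher and 5 lower (median 0.078, percentile 69.5): Thbs1 lay higher by 2.17 and Tnc by 2.02, and Thbs2 read -3.40, Postn -3.15 and Col15a1 -2.33. Altogether 18 of the lists lay outside 95% of the random lists. Normexp lowered the medians of complement to 0.53, of pericyte markers to 0.33 and of epithelial-mesenchymal transition to 0.25. The T and NK cell list came to lie inside the random range with normexp, on probes well above background on all 5 arrays and on the deposited matrix (median down to 0.059), and the unfolded protein response on the last 2 of these (down to 0.15).

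The largest differences between the primaries among genes well above background on both arrays were Wnt10a (6.25), Aldh1a1 (6.17), Aldh3a1 (5.49), Mill1 (5.28), Cxcl1 (5.06), Myh6 (4.67), Tekt4 (4.64), Vwa1 (4.11), Myh4 (3.94) and Pvalb (3.91) on the higher side of the irradiated tumour. Of these, Wnt10a, Aldh3a1, Mill1, Cxcl1, Tekt4, Myh4 and Pvalb were also named above as lower in the nodules than in the irradiated primary. Both comparisons use the same irradiated array, so a high reading on that 1 array would add to both differences. Among the lowest were the metallothionein Mt3 (-7.00), Cyren (-6.53), Mrrf (-5.19), Cyp2d5 (-5.05), Tvp23a (-4.72), Gad1 (-4.56), Krtap13-2 (-4.47), Or51b6 (-4.16) and Fxyd3 (-4.13). As bounds, Mnda lay at least 92.1-fold, Fcrl2 at least 59.2-fold, Sox14 at least 49.6-fold and Ppfia4 at least 45.5-fold higher. Magea13 lay at least 132-fold, Slc46a2 at least 82.0-fold, Cyp2d1 at least 38.1-fold and Zfp2 at least 29.5-fold lower. Mt3, Cyren, Mrrf, Tvp23a, Krtap13-2, Or51b6 and Fxyd3 fell also in the nodules against the non-irradiated primary, by log2 changes of -5.66, -6.56, -4.64, -4.71, -3.94, -3.57 and -5.08 (limma adjusted p from 0.0074 for Cyren to 0.0467 for Mt3, and 0.0542 or more without nodule 2). They were picked for their difference between the primaries and both comparisons use the same non-irradiated array, so a high reading on that 1 array gives both falls. In all, 3030 of 18442 features (16.4%) differed at least 2-fold, 1716 higher and 1314 lower in the irradiated tumour, and 785 at least 4-fold. Pairs of nodules differed at least 2-fold in 416 to 1297 features. Background correction by normexp left 1495 such features between the primaries, and a limma contrast that lends both tumours the spread of the nodules called 835.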

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

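The alternatives were set before the data were examined, except normexp on median spot signals and the summary of nodule pairs by their median, chosen after. No paired analysis was possible because each primary is 1 array and the labels do not say which samples share an animal. The cause was not tested except where named. Genes called against the irradiated primary (704) numbered 438 with median scaling, which moved the median of all genes from 0.034 to 0.13, 399 without an intensity trend, and 0 to 3232 leaving out 1 nodule, against 510 to 962 in the other settings. Leaving out a nodule removes 1 of the 2 residual degrees of freedom, so these counts turn on how alike the remaining pair is. Calls against the non-irradiated primary (3512) numbered 2123 at 2-fold or more and 0 to 6472 leaving out 1 nodule. Shared calls (302) numbered 200 without a trend and 0 to 1663 leaving out 1. The 2-fold differences between primaries (3030) became 1495 with normexp, 785 at 4-fold and 835 by a limma contrast. Those between nodules (959, median pair) became 408 with normexp, 607 on probes well above background on all 5 arrays, 598 on the deposited matrix, and 424 to 1305 leaving out 1. Called lists against the irradiated primary (12) numbered 0 with an estimated correlation, 6 by fry and 13 to 18 leaving out 1. Against the non-irradiated primary (5) they numbered 0 with an estimated correlation and 0 by fry, 9 with no filter, and 5 to 8 leaving out 1. Lists outside the random range (18) numbered 17 or 18. All 78 genes tested and named against the irradiated primary lost their call without nodule 2 (adjusted p 0.0501 to 0.218) and 46 without nodule 3 (0.0249 to 0.131). Apart from the run without nodule 2, 27 kept it in each setting that measured them (the deposited matrix holds 60 of the 78, and 62 were well above background on all 5 arrays), and 36 lost it without a trend, 22 with median scaling, 17 with no filter and 16 with quantile normalization. Against the non-irradiated primary 61 named genes lost theirs without nodule 2 and 25 without nodule 3, and 1 turned, Aif1 (-0.59 as the mean of its probes). Lists that passed no test turned camera's direction, listed here with their median. With no filter on dim probes, against the non-irradiated primary: interferon -0.10, cytokines -0.096, glycolysis -0.093, oxidative phosphorylation -0.030, matrix proteases 0.024, glial -0.12, skin -0.12, fat 0.052; against the irradiated primary: complement -0.035, oxidative phosphorylation -0.015. On probes well above background on all 5 arrays: interferon -0.017 and alveolar type 2 -0.79 (non-irradiated), complement 0.094, glial 0.13 and alveolar type 2 0.11 (irradiated). On the deposited matrix: interferon -0.014 and alveolar type 2 -0.86 (non-irradiated), complement 0.10, glial 0.19 and alveolar type 2 0.16 (irradiated). With normexp: glycolysis -0.073 and alveolar type 2 -0.11 (non-irradiated), alveolar type 2 0.15 (irradiated). With median scaling: alveolar type 2 0.35 (irradiated). With every probe kept: glial 0.044, alveolar type 2 -0.055 and fat 0.051 (non-irradiated), pericyte 0.24 (irradiated). Without a trend: cytokines -0.096 and B cells 0.28, and with quantile normalization B cells 0.27 (non-irradiated). Leaving out 1 nodule turned, against the irradiated primary, class II (range -0.38 to 0.22), complement (-0.11 to 0.18), oxidative phosphorylation (-0.045 to 0.021), alveolar type 2 (0.040 to 0.55), pericyte (-0.061 to 0.52) and fat (0.17 to 0.54). Against the non-irradiated primary it turned cytokines (-0.18 to 0.051), ribosomal proteins (-0.027 to 0.091), glial (-0.086 to 0.11), alveolar type 2 (-0.34 to 0.94), B cells (0.19 to 0.37) and fat (-0.022 to 0.13, with 0.028 without nodule 2). Of the other comparisons of a list with its alternatives, 353 against the irradiated and 350 against the non-irradiated primary kept direction and side of the threshold. Medians also moved without turning. Leaving out 1 nodule gave 0.051 to 0.22 for DNA repair and -0.14 to -0.041 for heat shock and immediate early genes (irradiated). Signal over background limits the dim genes: 69.8 to 73.5% of spots were well above it, and folds of the others are bounds.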

Other observations

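Several lists passed no test between the nodules and the irradiated primary. Some of their medians changed sign when 1 nodule was left out. Ribosomal proteins ran from -0.0052 to 0.13, angiogenesis from -0.16 to 0.050 and epithelial-mesenchymal transition from -0.17 to 0.10. Oxidative phosphorylation genes had a median of -0.015 (0 of 30 past limma, camera adjusted p = 0.637), ribosomal proteins 0.051 (0 of 33, adjusted p = 0.619) and housekeeping genes -0.053 (0 of 17, adjusted p = 0.159). Class II antigen presentation had a median of -0.20 (0 of 10, adjusted p = 0.443; 0.22 without nodule 3). Of 23 angiogenesis genes Angptl4 and Thbs1 fell, as given above (median -0.12, adjusted p = 0.49), and of 21 epithelial-mesenchymal transition genes 1 fell (median -0.12, adjusted p = 0.36). Endothelial markers had a median of 0.56 (0 of 15, adjusted p = 0.131; 0.21 to 0.94 over the other processing settings) and neutrophil markers 0.63 (0 of 10, adjusted p = 0.31), which was -0.12 with no filter on dim probes and 1.39, with a camera call, without nodule 3. Mast cell and platelet markers had a median of -0.30 (0 of 9, adjusted p = 0.29; -0.51 without nodule 2) and B cell markers a median of -9e-04 (0 of 8, adjusted p = 0.636). Among 7 skin markers Dmkn rose and Krt79 fell by 3.26 (adjusted p = 0.0128), and among 9 fat cell markers Pnpla2 rose by 1.02 (adjusted p = 0.0491); both calls were lost without nodule 2 (adjusted p from 0.0501), and that of Pnpla2 in 4 other processing settings (up to 0.0975).

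Against the non-irradiated primary the nodules also differed in single members of lists that passed no list test. RT1-A2 fell by 1.16 and RT1-CE16 fell by 1.00, the nuclear receptor Nr4a2 rose by 2.04, Col3a1 by 1.38 and Eln by 0.82, and all were lost without nodule 2 (adjusted p from 0.0542). Airway markers had a median of 2.21 (camera adjusted p = 0.0623), which was 1.64 with dim values at their bounds, 0.74 with normexp and 4.18, with a camera call, without nodule 3. DNA repair genes had a median of 0.38 (adjusted p = 0.0623), and 0.25 with a call with normexp, and collagens and matrix 0.49 (adjusted p = 0.0869).

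Of the tests that follow, the one on cardiac markers was chosen before its result was seen and the other 5 only after. Their 95% intervals run over the genes of a list, taken as independent, and do not measure the spread between samples. Heart myosin RNA was high in nodule 3 alone among the nodules, and heart muscle tissue in that sample may be its source. Of 20 heart markers, none of them in the lists above, 15 were measured and lay higher in nodule 3 than in the mean of nodules 1 and 2 by a median of 1.099 (95% interval 0.46 to 4.93), just short of the margin of 0.5 set for the lower end. Myl7 (7.36), Tnni3 (5.24), Sln (4.93) and Myl4 (4.36) lay far higher, but Ryr2 (0.02), Nkx2-5 (-0.30) and Hcn4 (-0.34) did not, so the source stays open. A panel of fast skeletal muscle markers argued against that tissue as the source: they lay higher by a median of only 0.041 over 11 genes (-0.22 to 0.88), against 6.15 and 6.80 for the heart myosins. Within the panel Ckm lay higher by 2.15. Muscle of other fibre types was not tested. Some muscle markers outside that panel read higher in nodule 3, such as Tcap (0.083, against -3.40 and -3.18 in nodules 1 and 2). The fast light chain Myl1, also outside the panel, did so as well (-3.68, against -8.48 and -8.24), so the panel does not speak for every fast marker. Other muscle markers did not read higher there, such as Tnnt1 (-3.42, against -2.83 and -3.59). The design names no biological explanation to test.

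Hypoxia genes were lower in the nodules than in the irradiated primary, which also held more skeletal muscle RNA. The 22 hypoxia genes outside glycolysis had a median of -1.03 (-1.70 to -0.49), but they are most of the list itself and muscle expresses some of them, so muscle as a source stays open. A state of the 1 irradiated tumour may contribute: against the non-irradiated primary the 28 hypoxia genes had a median of -0.17 (-0.52 to 0.09), an interval that includes 0 and decides neither way. The tissue site, the irradiation, the slide row and the different timing of the non-irradiated tumour stay open, as 1 tumour stands for each.

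Interferon-stimulated genes were lower in the nodules than in the irradiated primary (median -0.79, -1.39 to -0.23). The 25 macrophage markers had a median of -0.14 (-0.41 to 0.26), whose interval overlaps that of the interferon-stimulated genes, so fewer macrophages in the nodules stay open as a cause. Leaving out 1 nodule gave macrophage medians of -0.23 to -0.011. Against the non-irradiated primary the 31 interferon-stimulated genes had a median of -0.14 (-0.53 to 0.46), so a state of the irradiated tumour alone may lie behind the difference, but the interval does not decide it. Irradiation itself, the different timing of the non-irradiated tumour, the site of growth and the mouse that bore the tumour remain open and untested.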
